A study of Mus musculus with 29 samples.

How the data were processed

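RNA was measured in 29 mouse libraries: 8 of isolated crypts, 12 of tissue and 9 of organoids. Per the labels, libraries were made with the TruSeq stranded mRNA kit from 500 ng of total RNA extracted with RNeasy Mini and QIAshredder columns, and mice were of the C57BL/6 strain. Per the submitters' processing notes, the tools were cutadapt 1.5 and 1.9, Trimmomatic 0.36, TopHat2 2.0.14 and HTSeq (version not given), on the GRCm38 build. Their roles, settings and annotation release are not stated. The counts deposited by the authors are raw read counts per Ensembl gene with no normalization, and whole numbers in every file. The closing summary lines of HTSeq in the crypt files were left out. Gene symbols, types and coordinates came from GENCODE M21 on GRCm38, which matched 47310 of 47729 gene identifiers in the crypt files, and unmatched identifiers held 0.0323% of crypt counts and 0.0479% of tissue counts. Groups followed the genotype, tissue and titles in the labels. Organoid controls are titled as wild type and carry a floxed genotype, and floxed tissue is labelled as adjacent normal tissue. Both were used as controls.

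Each set was fitted alone with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group design, TMM scaling, and the robust quasi-likelihood F test with 1 coefficient per group. P values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was called a change. Expression is in CPM (counts scaled to a common library total) with TMM factors, with a prior count of 2 for log2 values. The SE of a log2 fold change is its size divided by the square root of the F statistic. Values after ± are the SD for CPM and the SE for log2 fold changes. The interaction contrast used the 8 crypt and 6 organoid libraries of control and H2BdIEC together. Tumor and adjacent libraries of 1 mouse share an animal, and a fit with mouse as a block was an alternative, as was a fit with the organoid letter as a block. The labels do not tie the 3 organoid libraries of a genotype to separate mice, so p values there measure only the spread between these libraries, which may be technical. Over genes, pairs of H2Bp53dIEC libraries differed by a chi-square per degree of freedom of 1.93 to 2.69, pairs of control organoids by 7.78 to 7.97, pairs of H2BdIEC organoids by 3.63 to 17.8 and pairs of crypt libraries of 1 group by 21.3 to 210. The number of replicates is 4 per group in crypts and tissue and 3 in organoids, and the depth per library limits precision most in tissue control 1320 and organoid H2BdIEC A.

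A total of 36 gene lists was fixed before the data were examined, of which 27 are described in at least 1 comparison. The choice of lists to describe in each comparison and of the genes to print was made after their results were seen. For each list the members called higher and lower were counted over all genes and adjusted over the list alone. Lists of at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of the camera calls printed, those of the p53 list held with an estimated correlation in crypts and in both H2Bp53dIEC comparisons, and those of the Wnt list in both H2Bp53dIEC comparisons. The rotation test fry was run on the same lists as an alternative.

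Named genes followed a rule fixed in advance: Rnaseh2b and Trp53, the 8 protein-coding genes with the largest increase and the 8 with the largest decrease among those that changed, had a mean log2 CPM of at least 3, and had every library of 1 group above every library of the other, and for each described list the 4 members with the smallest p (8 for p53 targets). Gene models without a standard symbol, Xist and Y-linked genes were left out of that rule. For the interaction, the condition on separate libraries cannot apply, and average log CPM replaced the mean over 2 groups. In the genes printed as risen or fallen every library of 1 group lay above every library of the other, outside the interaction. Chance alone gives such a separation for 1 of the 35 splits of 4 against 4 libraries and 1 of the 10 splits of 3 against 3.

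Alternatives planned in advance were DESeq2 1.42.0 (size factors alone, and its own test), upper-quartile factors, no low-count filter, at least 1 CPM, robust=FALSE, only the 2 groups compared, the replicate blocks, and leaving out each library in turn. Where 1 library was left out, the spread was pooled over the remaining libraries. Added after seeing the data were sex and the proximal marker score as covariates, thinning to equal depth, leaving out X and Y genes, control 1320, adjacent 1323, or both libraries of a mouse. The pipeline was tested on simulated data with known changes, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Replicate pairs were checked for repeated deposits over genes with at least 20 counts, and 0 pairs were identical.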

Results

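Poly(A)-selected, strand-specific RNA sequencing measured gene expression in 29 mouse libraries that fall into 8 groups. The crypt set held isolated epithelial crypts of mice aged 52 weeks, 4 from floxed controls and 4 from H2BdIEC mice, the genotype name given in the labels. The tissue set held 4 tumors and 4 samples of adjacent non-tumor tissue from the same 4 H2B/p53dIEC mice, and 4 samples of non-tumor tissue from floxed mice, called controls here. The organoid set held 3 libraries each of control, H2BdIEC and H2Bp53dIEC intestinal organoids. Gene counts per library totalled 23118463 to 25913155 in crypt controls and 15545059 to 18817537 in H2BdIEC crypts. They totalled 22370148 to 34086149 in adjacent tissue and 21884287 to 30290711 in tumors. Tissue controls held 26853485 to 41504298, except control 1320 with 401365. Organoids held 16803119 to 21386586 in controls and 13549741 to 15844236 in H2Bp53dIEC. The H2BdIEC organoids held 5774771, 13219451 and 15136734 in replicates A, B and C.

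The labels name p53 in H2B/p53dIEC, taken to be Trp53. H2B was read as Rnaseh2b from the series title and from the lower Rnaseh2b counts, so that lower level is not independent evidence of the deletion. Rnaseh2b, which encodes a subunit of RNase H2, the enzyme that starts ribonucleotide excision repair, was lower in crypts, tissue and organoids of these genotypes than in controls. In crypts it stood at 2.50 ± 0.274 against 10.6 ± 4.02 CPM (SD, n = 4 each; log2 fold change -2.08 ± 0.27, adjusted p = 0.00229, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Adjacent tissue held 4.12 ± 1.23 against 16.1 ± 5.34 CPM in tissue controls (SD, n = 4 each, log2 fold change -1.86 ± 0.35, adjusted p = 0.0292), and tumors held 4.39 CPM (-1.77 ± 0.34, adjusted p = 0.000980 against controls). H2BdIEC organoids held 5.83 ± 1.08 against 16.6 ± 1.75 CPM (SD, n = 3 each, -1.47 ± 0.17, adjusted p = 0.000502) and H2Bp53dIEC organoids held 1.65 ± 0.539 CPM (-1.82 ± 0.23, adjusted p = 0.000147 against H2BdIEC). Trp53, which encodes p53, stood at 11.1 ± 0.956 against 95.7 ± 16.2 CPM in H2Bp53dIEC and H2BdIEC organoids (SD, n = 3 each, -3.13 ± 0.13, adjusted p = 1.41e-08). In tissue, Trp53 fell in tumors against controls (19.8 against 44.8 CPM, -1.17 ± 0.28, adjusted p = 0.00342), and adjacent tissue held 21.3 CPM (-1.07 ± 0.28, adjusted p = 0.0777 against controls). Crypts and H2BdIEC organoids showed no difference in Trp53 that passed the test (log2 -0.28 ± 0.11 and -0.15 ± 0.11, adjusted p = 0.126 and 0.479). On GRCm38, Rnaseh2b (ENSMUSG00000021932) spans chromosome 14, 62292589 to 62372992, and Trp53 (ENSMUSG00000059552) spans chromosome 11, 69580359 to 69591873. Counts are per gene, so reads from exons outside a deletion stay counted. The call of Rnaseh2b in adjacent tissue was lost when adjacent 1349 or any 1 of controls 1315, 1316, 1320 and 1321 was left out, with adjusted p from 0.0453 to 0.112 over the 8 removals of 1 library, and with control 1320 and adjacent 1323 both left out. That last fit was chosen after seeing the data.

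**Figure D1:**
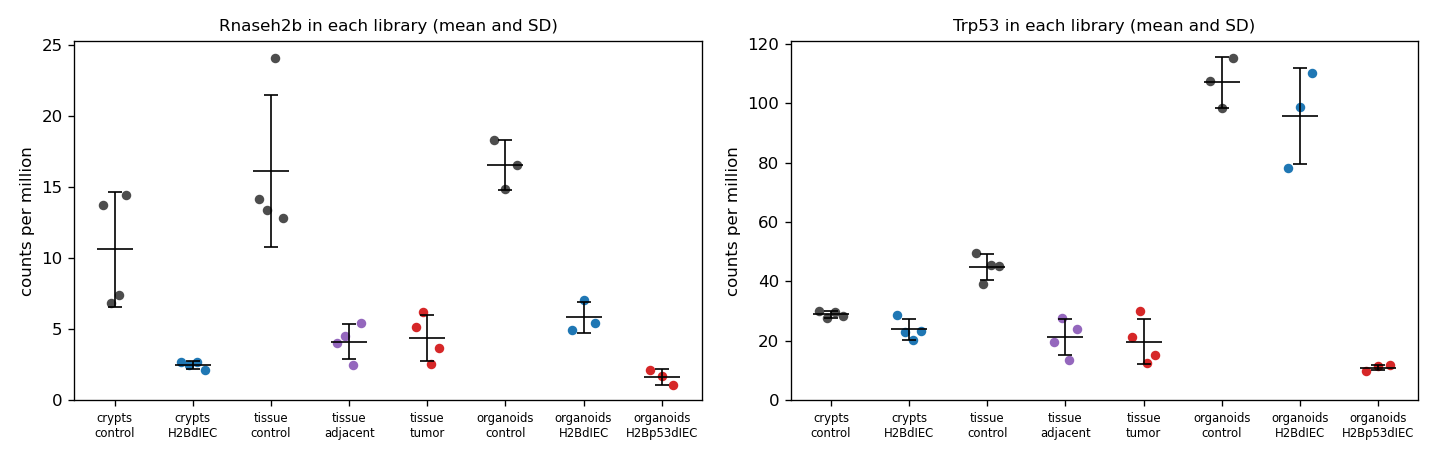
CPM (vertical axes) of Rnaseh2b and Trp53 in each library of the 8 groups, with the mean (long bar) and SD (whiskers) of 3 or 4 libraries. Rnaseh2b averaged 10.6, 16.1 and 16.6 CPM in the control groups of crypts, tissue and organoids, and Trp53 averaged 11.1 CPM in H2Bp53dIEC organoids.

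The first comparison asked how gene expression in crypts of aged mice differed between H2BdIEC and floxed mice. Transcriptional targets of p53 were higher together: 22 of 39 tested targets rose and 0 fell (27 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.68. For p53 targets, camera gave an adjusted p of 5.35e-15, and adjusted p = 0.00753 with an estimated correlation. Phlda3, an inhibitor of AKT signalling, rose by 4.18 ± 0.39 on the log2 scale (13.1 against 0.731 CPM, adjusted p = 0.000493). Eda2r, a gene of the tumor necrosis factor receptor family, rose by 2.83 ± 0.24 (13.6 against 1.93 CPM, adjusted p = 0.000230). Ccng1, which encodes cyclin G1, went from 79.7 to 208 CPM (log2 1.38 ± 0.16, adjusted p = 0.00130). Zmat3 (1.49 ± 0.11, adjusted p = 0.000133), Psrc1 (2.60 ± 0.23, 0.000378), the noncoding RNA gene Pvt1 (2.49 ± 0.22, 0.000285), Ephx1 (2.59 ± 0.30, 0.00245) and the cytokine gene Gdf15 (1.81 ± 0.22, 0.00167) rose too. The long noncoding RNA Trp53cor1 (lincRNA-p21) rose from a low level (1.56 against 0.0752 CPM, log2 4.26 ± 0.39, adjusted p = 0.000378). No removal of a single library moved the count of 22 by over 1.5 times, and its range over these removals was 18 to 24. On GRCm38, Phlda3 (ENSMUSG00000041801) spans chromosome 1, 135766119 to 135769136, Eda2r (ENSMUSG00000034457) spans chromosome X, 97333840 to 97377216, and Ccng1 (ENSMUSG00000020326) spans chromosome 11, 40748552 to 40755311.

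Interferon-stimulated genes were also higher in H2BdIEC crypts, with 13 of 30 risen and 0 fallen (22 adjusted over the list alone, median log2 0.68). Camera on interferon-stimulated genes gave an adjusted p of 2.97e-11, and adjusted p = 0.436 with an estimated correlation. Among those that rose were the 2'-5' oligoadenylate synthetase gene Oas2 (1.41 ± 0.19, adjusted p = 0.00245), Stat2, which encodes a transcription factor of the interferon response (0.97 ± 0.16, 0.00767), Rtp4 (1.0 ± 0.16, 0.00538) and Oasl1 (0.85 ± 0.14, 0.00689). The count was 6 without control 3 and 7 without H2BdIEC 4. Markers of intestinal stem cells were lower: 6 of 18 fell (7 adjusted over the list alone). For intestinal stem cells, camera gave an adjusted p of 3.34e-05, and adjusted p = 0.436 with an estimated correlation. Olfm4 went from 554 to 172 CPM (log2 -1.69 ± 0.18, adjusted p = 0.000641), Lgr5, the Wnt-amplifying receptor of crypt base stem cells, from 17.5 to 5.37 CPM (-1.70 ± 0.23, adjusted p = 0.00283), and Smoc2 changed by -0.94 ± 0.13 (0.00326). The stem cell count was 3 without control 3 or without H2BdIEC 4. The enterocyte list averaged 10.89 log2 CPM in H2BdIEC libraries (10.69 to 11.12) and 10.40 in controls (10.15 to 10.72). These ranges overlapped, and no test of this list in crypts is given here. Of 26 G2/M genes 3 fell (Nusap1, Ccnb2 and Ccna2, 8 adjusted over the list alone). Camera on G2/M phase genes gave an adjusted p of 3.84e-06, and adjusted p = 0.514 with an estimated correlation. The G2/M count was 0 without control 1, control 3 or H2BdIEC 4, 1 without H2BdIEC 2 or 3, and 7 without H2BdIEC 1. With all libraries it was 8 by DESeq2 and 7 with no low-count filter.

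Of 13 tested Paneth cell markers 9 fell in H2BdIEC crypts (11 adjusted over the list alone), among them the lysozyme gene Lyz1 (1190.5 against 3661 CPM, log2 -1.62 ± 0.24, adjusted p = 0.00401) and the defensin genes Defa24 (-1.92 ± 0.40, 0.0202), Defa21 (-2.21 ± 0.44, 0.0215) and Defa26 (-2.28 ± 0.46, 0.0238). For Paneth cells, camera gave an adjusted p of 4.41e-07, and adjusted p = 0.436 with an estimated correlation. Near-identical defensin copies share reads, so the level of each single copy is uncertain. The Paneth count was 3 without control 1, H2BdIEC 1 or H2BdIEC 3, 1 without control 3 or H2BdIEC 4, 5 without control 4, and 1 with no low-count filter. Of 15 goblet cell markers 7 fell (11 adjusted over the list alone), with the mucin gene Muc2 at a log2 fold change of -1.09 ± 0.22, adjusted p = 0.0154, Ccl6 at -1.40 ± 0.22 and the glycosyltransferase gene Galnt12 at -0.88 ± 0.15 (adjusted p = 0.00689 and 0.00688). Camera on goblet cells gave an adjusted p of 9.55e-07, and adjusted p = 0.436 with an estimated correlation. The goblet count was 3 without H2BdIEC 4. The gasdermin gene Gsdmc4 fell by 5.39 on the log2 scale (4.58 against 192 CPM, adjusted p = 0.0300), Bmp3, a bone morphogenetic protein gene, by 3.22 (6.73 against 63.0 CPM, adjusted p = 0.000493) and Cstf2t by 1.94 (adjusted p = 0.000493). Without control 4 the log2 fold change of Gsdmc4 was -4.27.

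Among NRF2 targets, 8 of 18 rose and 1 fell (11 rose adjusted over the list alone), with the glutathione transferase genes Gsta3 (4.28 ± 0.37, adjusted p = 0.000521) and Gsta4 (2.25 ± 0.32, 0.00708) among the risen. For NRF2 targets, camera gave an adjusted p of 5.93e-06, and adjusted p = 0.436 with an estimated correlation. Reads shared between glutathione transferase copies make single members uncertain, and the count was 5 without control 3 or with no low-count filter. Of 17 fetal-like and YAP target genes 4 rose and 1 fell (9 rose adjusted over the list alone), including the interleukin receptor antagonist gene Il1rn (2.11 ± 0.31, 0.00374) and the epiregulin gene Ereg (1.9 ± 0.28, 0.00401), and 2 rose without control 3. Camera on fetal-like and YAP targets gave an adjusted p of 0.00275, and adjusted p = 0.436 with an estimated correlation. Single genes with large increases were the alkaline phosphatase gene Akp3 (1020.2 against 6.56 CPM, log2 7.29 ± 1.14, adjusted p = 0.0145), the calcium-binding protein gene S100g (133 against 2.06 CPM, 6.04 ± 0.87, adjusted p = 0.0114), the iron exporter gene Slc40a1 (139 against 7.96 CPM, 4.13 ± 0.56, adjusted p = 0.00810), the skeletal actin gene Acta1 (3.07 ± 0.23, 0.000197) and the metallothionein gene Mt1 (2.79 ± 0.22, 0.000197). Without control 4, the log2 fold change of Akp3 was 7.94 and that of S100g 6.64. Slc40a1 belongs to the fixed list of proximal small intestine genes, described next, so its rise may go with region. Akp3, S100g, Acta1 and Mt1 lie outside that list, but their rise was not separated from region either.

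The H2BdIEC crypts also differed from controls in markers of region and of other tissue. The proximal small intestine list averaged 6.60 to 7.24 log2 CPM in H2BdIEC libraries and 5.50 to 6.20 in controls, with 3 of 10 members risen (4 adjusted over the list alone). For proximal small intestine genes, camera gave an adjusted p of 0.00273, and adjusted p = 0.436 with an estimated correlation. The risen proximal genes included Pdx1, a transcription factor gene of duodenum and pancreas (17.6 against 1.11 CPM, log2 4.0 ± 0.71, adjusted p = 0.0171), and the fatty acid binding protein gene Fabp1 (1.18 ± 0.29, 0.0314), and the count was 1 without control 1 or without H2BdIEC 4. The 4 tested genes of stomach and Brunner glands averaged 0.56 to 1.47 log2 CPM in H2BdIEC libraries and -1.50 to -0.90 in controls. Acinar pancreas transcripts averaged 1.17 to 5.70 log2 CPM in H2BdIEC libraries, highest in H2BdIEC 2, and -1.49 to -1.26 in controls. By edgeR, 0 of 8 pancreas genes passed the adjusted test, while 7 were higher and 1 lower at unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower and gave 6 no adjusted p. Camera on pancreas genes gave an adjusted p of 0.000415, and adjusted p = 0.436 with an estimated correlation. Without H2BdIEC 2 or with robust=FALSE 7 rose, and adjusted over the list alone 7 rose and 1 fell. Mitochondrially encoded genes, ribosomal RNA included, took 9.30% to 15.7% of counts in H2BdIEC crypts, 4.33% to 5.09% in controls 1 to 3 and 10.4% in control 4. The ribosomal RNA gene mt-Rnr2 alone took 6.35% to 10.5%, 2.79% to 3.27% and 7.45%. Of the 13 protein-coding mitochondrial genes of the fixed list 7 rose (11 adjusted over the list alone), with mt-Co1 at 1.16 ± 0.28 (0.0298). But 0 rose without control 1 or control 3, 1 without H2BdIEC 4, 2 without H2BdIEC 2, 3 without H2BdIEC 3 and 4 without control 2. For mitochondrially encoded genes, camera gave an adjusted p of 9.74e-07, and adjusted p = 0.436 with an estimated correlation.

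**Figure D2:**
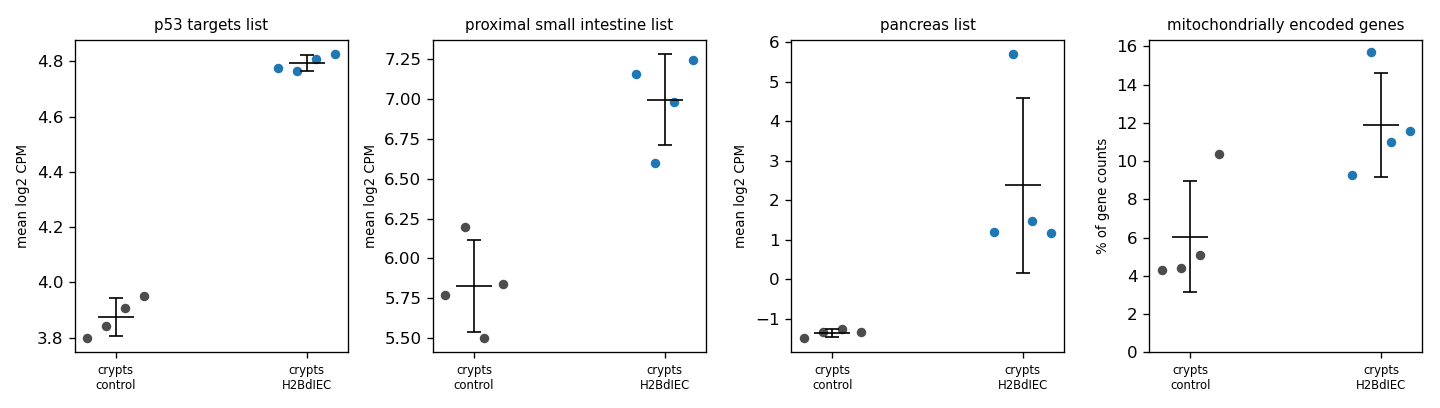
Mean log2 CPM of the p53 target, proximal small intestine and pancreas lists, and the share of gene counts from mitochondrially encoded genes (%, ribosomal RNA included), in each crypt library, with the mean (long bar) and SD (whiskers) of 4 libraries per group. The p53 list ranged from 3.8 to 3.95 in controls and from 4.76 to 4.83 in H2BdIEC crypts.

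Over all 14596 genes tested in crypts by edgeR, 1464 changed, 753 higher and 711 lower (700 and 754 with upper-quartile factors), and DESeq2 called 2390. The count was 481 without control 3, 508 without H2BdIEC 4, 656 without control 1 and 967 without H2BdIEC 3. With the mean of the proximal list as a covariate, a fit chosen after seeing the data, 11 genes passed by edgeR, 1 of them a p53 target (Psrc1), against 1255 at unadjusted p under 0.05, and 3 of the 11 were among the 1464. In that fit 7 pancreas genes rose, and 0 genes passed in the direction described for each of the interferon-stimulated, stem, Paneth, goblet, NRF2, fetal-like, G2/M, mitochondrial and proximal lists. DESeq2 was not run with that covariate. The median log2 fold change of all 39 tested p53 targets was 0.671 with the covariate and 0.683 without it. Their median SE was 0.367 and 0.146. Of 55 named genes that passed, 32 passed under every planned setting, and the removals of control 3, H2BdIEC 4, control 1, H2BdIEC 3 and H2BdIEC 2 ended the calls of 21, 19, 17, 12 and 11 of them.

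Tumors of H2B/p53dIEC mice were compared with adjacent tissue of the same mice to ask which genes marked the tumors. Wnt target genes were higher: 21 of 23 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 2.88. Camera on Wnt targets gave an adjusted p of 1.10e-10, and adjusted p = 0.151 with an estimated correlation. Notum, which encodes a secreted Wnt deacylase, stood at 457 against 0.415 CPM (log2 10.10 ± 0.72, adjusted p = 4.48e-06), and the Wnt inhibitor gene Wif1 at 186 against 0.697 CPM (8.04 ± 0.74, adjusted p = 1.60e-05). For Notum, tumor 1322 held 1121 CPM and the other 3 tumors 195 to 293, and the log2 fold change was 9.15 without tumor 1322, as it was 7.43 for Wif1. The transcription factor gene Prox1 rose by 4.55 ± 0.41 (1.48e-05) and Cd44, a hyaluronan receptor gene, by 2.88 ± 0.27 (1.57e-05). Stem cell markers rose in 15 of 18 cases (15 adjusted over the list alone), including Smoc2 (609 against 64.4 CPM, 3.24 ± 0.15, adjusted p = 3.04e-07), Lgr5 (106 against 9.61 CPM, 3.46 ± 0.33, adjusted p = 1.60e-05), Prom1 (3.56 ± 0.39, 3.60e-05) and Sox4 (2.87 ± 0.18, 2.62e-06). For intestinal stem cells, camera gave an adjusted p of 5.31e-09, and adjusted p = 0.253 with an estimated correlation. The lists of Wnt targets and stem cells share members such as Lgr5. Both counts stayed at 21 and 15 in every removal of a single library. On GRCm38, Notum (ENSMUSG00000042988) spans chromosome 11, 120653788 to 120661175, Smoc2 (ENSMUSG00000023886) spans chromosome 17, 14279506 to 14404790, and Lgr5 (ENSMUSG00000020140) spans chromosome 10, 115450311 to 115587780.

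All 11 tested genes of stomach and Brunner glands rose in tumors (11 adjusted over the list alone). Camera on gastric and Brunner gland genes gave an adjusted p of 4.23e-11, and adjusted p = 0.0517 with an estimated correlation. The gastrokine gene Gkn3 stood at 437 against 0.319 CPM (log2 10.39 ± 1.01, adjusted p = 2.09e-05), the mucin gene Muc6 at 621 against 0.596 CPM (10.03 ± 0.94, adjusted p = 1.82e-05) and the cathepsin E gene Ctse at 314 against 2.13 CPM (7.21 ± 0.55, adjusted p = 6.39e-06). The water channel gene Aqp5 (442 against 0.415 CPM, 10.03 ± 0.56, adjusted p = 1.62e-06) and Bpifb1 (695 against 0.498 CPM, 10.46 ± 1.36, adjusted p = 0.000116) rose as well. For Bpifb1, tumor 1322 held 2411 CPM and the other 3 tumors 52.9 to 161, and the log2 fold change was 7.96 without tumor 1322. That of Muc6 was 9.37 without tumor 1319. Genes of the ileum were lower, 8 of 10 (9 adjusted over the list alone), with the bile acid transporter gene Slc10a2 at 7.46 against 842 CPM (-6.82 ± 1.12, adjusted p = 0.000505) and Cubn, an intestinal receptor gene for the vitamin B12 complex, at 9.72 against 418 CPM (-5.43 ± 0.50, adjusted p = 1.60e-05). For ileum genes, camera gave an adjusted p of 8.56e-05, and adjusted p = 0.317 with an estimated correlation. Of 10 proximal genes 2 rose (Pdx1 5.74 ± 0.70 and Cybrd1 3.69 ± 0.51, adjusted p = 7.10e-05 and 0.000159) and 2 fell (2 and 2 adjusted over the list alone). Camera on proximal small intestine genes gave an adjusted p of 0.388, and adjusted p = 0.801 with an estimated correlation. Without the adjacent library of mouse 1323, 5 rose and 3 fell. The ileum list averaged 8.29, 7.81 and 8.11 log2 CPM in the adjacent tissue of mice 1349, 1322 and 1319. It averaged 5.60 in that of mouse 1323 and 1.85 to 4.17 in tumors, so ileum markers moved together with tumor against adjacent tissue. Proximal means rose from 2.79, 2.84 and 4.21 to 5.80, 3.65 and 5.96 in mice 1349, 1322 and 1319. In mouse 1323 the proximal mean fell from 5.22 to 3.48. Enterocyte genes fell in tumors too, so the ileum fall alone does not show a different region.

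Genes of inflammation rose in 22 of 24 cases (23 adjusted over the list alone, median log2 4.22), among them the cytokine genes Il11 (50.3 against 0.793 CPM, 6.00 ± 0.49, adjusted p = 7.19e-06) and Il6 (34.8 against 0.302 CPM, 6.80 ± 0.65, adjusted p = 1.94e-05) and the matrix metalloproteinase genes Mmp13 (4.44 ± 0.43, 1.95e-05) and Mmp10 (2.67 ± 0.31, 4.69e-05). For inflammation genes, camera gave an adjusted p of 4.23e-10, and adjusted p = 0.317 with an estimated correlation. Markers of myeloid cells averaged 5.25 to 6.39 log2 CPM in tumors, 3.44 to 5.47 in adjacent tissue and 3.77 to 4.57 in controls. Fetal-like and YAP target genes rose in 15 of 21 cases and fell in 1 (17 rose adjusted over the list alone), with the osteopontin gene Spp1 at 376 against 1.23 CPM (8.24 ± 0.60, adjusted p = 4.65e-06) and the alarmin gene Il33 at 90.7 against 11.3 CPM (3.01 ± 0.32, adjusted p = 2.99e-05). Camera on fetal-like and YAP targets gave an adjusted p of 1.34e-06, and adjusted p = 0.253 with an estimated correlation. Extracellular matrix and fibroblast genes rose in 15 of 20 cases and fell in 1 (16 rose adjusted over the list alone), such as the collagen genes Col12a1 (3.31 ± 0.43, 0.000118) and Col1a1 (1400.3 against 66.7 CPM, 4.39 ± 0.75, adjusted p = 0.000628), and 6 rose in the fit with mouse as a block. For extracellular matrix and fibroblasts, camera gave an adjusted p of 5.82e-05, and adjusted p = 0.538 with an estimated correlation. For Col1a1 the log2 fold change was 3.51 without tumor 1323 and 4.99 without adjacent 1322. Of 26 S-phase genes 17 rose and 1 fell (20 rose adjusted over the list alone, E2f1 1.62 ± 0.32, 0.00163), and 10 rose without both libraries of mouse 1322. Camera on S phase genes gave an adjusted p of 0.000125, and adjusted p = 0.538 with an estimated correlation. Of 26 G2/M genes 15 rose (19 adjusted over the list alone, Kif20a 1.51 ± 0.33, 0.00251), and 23 rose with mouse as a block. For G2/M phase genes, camera gave an adjusted p of 8.39e-06, and adjusted p = 0.538 with an estimated correlation.

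Smooth muscle genes all fell, 15 of 15 (15 adjusted over the list alone), among them Mylk (77.8 against 549.5 CPM, log2 -2.82 ± 0.36, adjusted p = 9.54e-05), Myl9 (-2.18 ± 0.24, 3.72e-05) and Acta2 (-1.83 ± 0.23, 7.64e-05). Camera on smooth muscle genes gave an adjusted p of 1.16e-08, and adjusted p = 0.317 with an estimated correlation. Of 14 genes of enteric neurons and glia 10 fell (10 adjusted over the list alone), such as the neuronal RNA-binding protein gene Elavl4 (-3.55 ± 0.38, 3.00e-05). For enteric neurons and glia, camera gave an adjusted p of 0.000410, and adjusted p = 0.393 with an estimated correlation. Of 24 enterocyte genes 15 fell (16 adjusted over the list alone). Camera on enterocytes gave an adjusted p of 2.69e-06, and adjusted p = 0.538 with an estimated correlation. The brush border peptidase genes Anpep (723 against 9823 CPM, -3.76 ± 0.52, adjusted p = 0.000142), Mep1a (17.1 against 1497 CPM, -6.45 ± 0.84, adjusted p = 0.000115) and Dpp4 (-3.73 ± 0.64, 0.000662) and the villin gene Vil1 (-2.67 ± 0.40, 0.000249) were among them. The enterocyte count was 9 with no low-count filter, 8 with mouse as a block and 8 without both libraries of mouse 1323. Of 17 enteroendocrine genes 8 fell (8 adjusted over the list alone), including the hormone genes Nts (-3.99 ± 0.47, 6.00e-05) and Pyy (-4.54 ± 0.65, 0.000207), and 13 fell without tumor 1319. For enteroendocrine cells, camera gave an adjusted p of 0.000810, and adjusted p = 0.538 with an estimated correlation. Paneth cell genes split, 4 higher and 8 lower of 13 (4 and 8 adjusted over the list alone): Mmp7 (1639.9 against 72.8 CPM, 4.49 ± 0.45, adjusted p = 2.07e-05) and Pla2g2a (4.33 ± 0.45, 2.97e-05) rose, and the defensin genes Defa21 (-5.71 ± 0.74, 0.000114) and Defa22 (-5.55 ± 0.76, 0.000161) fell. Camera on Paneth cells gave an adjusted p of 0.356, and adjusted p = 0.801 with an estimated correlation.

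Targets of p53 went both ways in tumors of these H2B/p53dIEC mice: 9 of 39 rose and 11 fell (9 and 12 adjusted over the list alone). For p53 targets, camera gave an adjusted p of 0.601, and adjusted p = 0.801 with an estimated correlation. Sesn1 (-2.29 ± 0.29, 8.62e-05), the cell cycle inhibitor gene Cdkn1a (117 against 507 CPM, -2.11 ± 0.32, adjusted p = 0.000254) and Perp (-1.49 ± 0.30, 0.00167) fell, while Bax (0.87 ± 0.16, 0.000861), Phlda3 (2.05 ± 0.43, 0.00209) and Aen (1.12 ± 0.24, 0.00220) rose. Without both libraries of mouse 1319 or of mouse 1322, 7 and 6 fell. Of 20 genes of the ATF4 and unfolded protein response 9 rose and 2 fell (10 rose adjusted over the list alone), with the serine synthesis gene Phgdh at 3.37 ± 0.40 (6.66e-05) and the amino acid transporter gene Slc7a5 at 2.67 ± 0.29 (3.64e-05). Camera on ATF4 and unfolded protein response genes gave an adjusted p of 0.00899, and adjusted p = 0.473 with an estimated correlation. By edgeR, 8293 of 17666 genes changed, 4059 higher and 4234 lower, or 4389 and 3958 with DESeq2 size factors and 4362 and 3989 with upper-quartile factors. With mouse as a block 6603 changed, 3648 higher and 2955 lower. Of 82 named genes that passed, 80 passed under every planned setting. The exceptions were lost with no low-count filter, and 1 of them with mouse as a block.

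**Figure D3:**
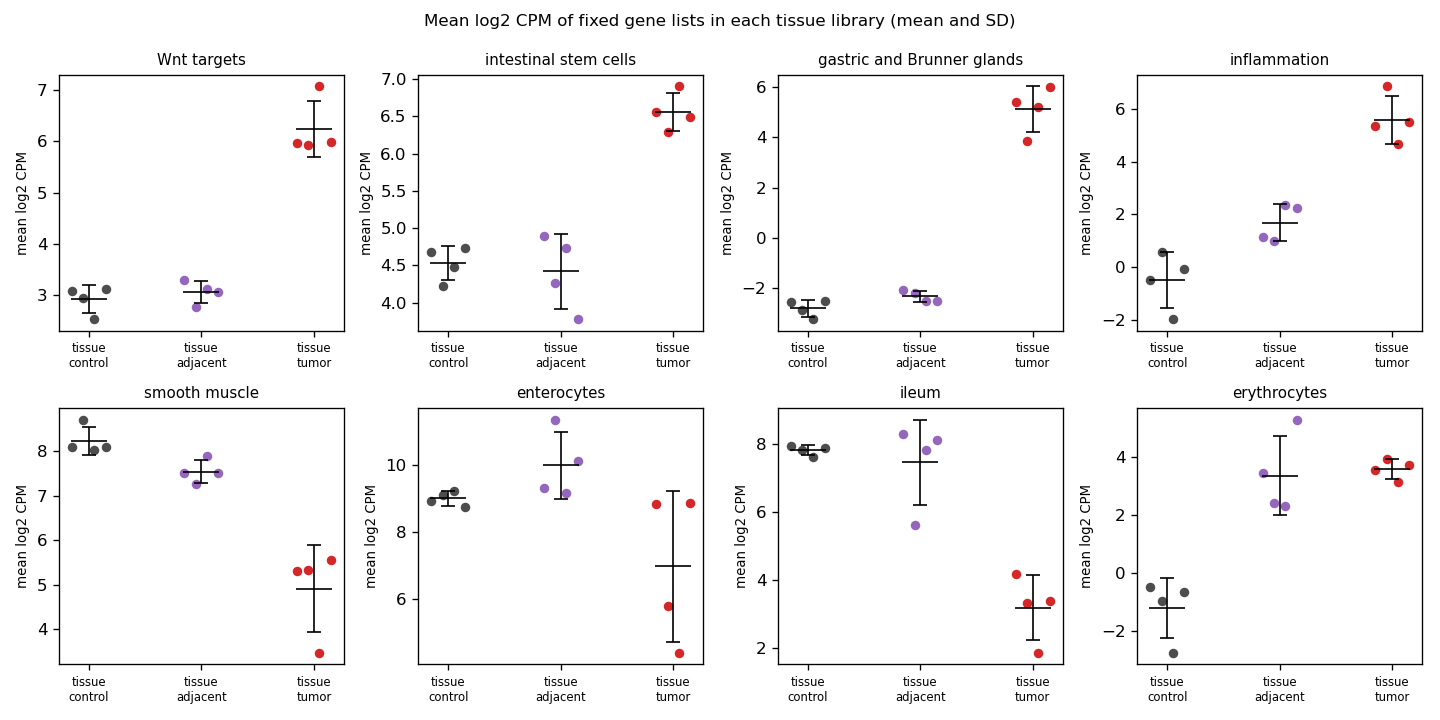
Mean log2 CPM of 8 fixed gene lists in each tissue library, with the mean (long bar) and SD (whiskers) of 4 libraries per group. Gastric and Brunner gland genes averaged 3.85 to 6.01 in tumors and -2.53 to -2.09 in adjacent tissue.

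Non-tumor tissue of H2B/p53dIEC mice was compared with that of floxed mice to ask what differed outside the tumors. Erythrocyte genes were higher in adjacent tissue, 7 of 7 (7 adjusted over the list alone), with the globin gene Hbb-bs at 149 against 4.17 CPM (log2 4.81 ± 0.67, adjusted p = 0.0146) and the heme synthesis gene Alas2 at 12.6 against 0.221 CPM (5.41 ± 0.77, adjusted p = 0.0146). For erythrocytes, camera gave an adjusted p of 1.34e-09, and adjusted p = 0.401 with an estimated correlation. Globin copies share reads. Of 15 endothelial genes 5 rose (12 adjusted over the list alone), such as the von Willebrand factor gene Vwf (2.11 ± 0.37, 0.0282) and Esam (1.13 ± 0.21, 0.0285), and of 24 inflammation genes 5 rose (9 adjusted over the list alone), among them the calprotectin genes S100a9 (44.3 against 0.212 CPM, 7.24 ± 0.95, adjusted p = 0.0146) and S100a8 (7.06 ± 1.02, 0.0146) and the lipocalin gene Lcn2 (59.4 against 2.55 CPM, 4.56 ± 0.84, adjusted p = 0.0292). Camera on endothelial genes gave an adjusted p of 8.71e-09, and adjusted p = 0.511 with an estimated correlation. For inflammation genes, camera gave an adjusted p of 1.24e-06, and adjusted p = 0.545 with an estimated correlation. Mt1 (3.60 ± 0.55, 0.0158) and the protease inhibitor gene Serpina3n (3.89 ± 0.70, 0.0285) rose. Interferon-stimulated genes were lower, 3 of 30 (15 adjusted over the list alone and 11 by DESeq2, median log2 -1.01), namely Ifit1 (7.36 against 60.1 CPM, -3.08 ± 0.58, adjusted p = 0.0303), Oas3 (-2.55 ± 0.48, 0.0302) and Oasl2 (-2.08 ± 0.45, 0.0490). Camera on interferon-stimulated genes gave an adjusted p of 1.18e-10, and adjusted p = 0.520 with an estimated correlation. Adjacent 1319 held Hbb-bs at 371 CPM (53.4 to 101 in the other 3), Alas2 at 32.6 CPM (4.40 to 8.41 in the other 3) and Lcn2 at 150.4 CPM (16.4 to 37.8 in the other 3), and without it their log2 fold changes were 3.81, 4.33 and 3.52. That of S100a8 was 6.41 without it too, that of Mt1 4.25 without control 1315 and that of Ifit1 -2.40 without control 1316. Smooth muscle genes averaged 7.25 to 7.88 log2 CPM in adjacent tissue and 8.02 to 8.70 in controls. The deiodinase gene Dio1 fell too (-3.93 ± 0.65, 0.0225). Among p53 targets 1 of 39 fell, Ccng1 (-0.90 ± 0.19, 0.0464, 1 adjusted over the list alone), and in each of the 8 removals of a single library 0 passed by edgeR, against 5 lower and 2 higher at unadjusted p under 0.05 with all libraries and 1 lower by DESeq2. For p53 targets, camera gave an adjusted p of 0.0358, and adjusted p = 0.520 with an estimated correlation.

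Adjacent tissue differed from controls in 189 of 17666 genes by edgeR (140 higher, 49 lower) and 902 by DESeq2. The edgeR count was 441 with only these groups in the fit, 0 without control 1321 (2075 at unadjusted p under 0.05), 2 without control 1316, 32 without control 1315, 53 without control 1320, 84 without adjacent 1349 and 89 without adjacent 1319, and 33 without control 1320 and adjacent 1323, a fit chosen after seeing the data. The erythrocyte count was 0 without control 1316 or 1321 and 2 without control 1315. The endothelial count was 0 without control 1315, 1316 or 1321 or adjacent 1349, 1 without control 1320, and 2 without adjacent 1319. With all libraries it was 9 by DESeq2 and 8 with only these groups in the fit. The inflammation count was 0 without control 1316 or 1321, 1 without control 1315, 2 without control 1320, and 3 without adjacent 1322 or 1319. Keeping all libraries gave 8 by DESeq2 and 3 with no low-count filter. The interferon-stimulated count was 0 without control 1316, 1320 or 1321 or adjacent 1349, 1323 or 1319. Of 28 named genes that passed, 0 passed under every planned setting of the edgeR and DESeq2 fits, and 18 passed under those that kept all libraries. The removals of controls 1316, 1321, 1315 and 1320 ended 28, 28, 21 and 18 of these calls, and those of adjacent 1349, 1319, 1323 and 1322 ended 17, 14, 7 and 4.

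Tumors were also compared with the tissue of floxed mice, a reference that shares no animals with them. The lists moved as against adjacent tissue: 20 of 23 Wnt targets (20 adjusted over the list alone), 14 of 18 stem cell genes (14), 11 of 11 gastric and Brunner gland genes (11), 23 of 24 inflammation genes (23) and 17 of 21 fetal-like and YAP targets (18) rose. Camera on Wnt targets gave an adjusted p of 1.51e-07, and adjusted p = 0.359 with an estimated correlation. For intestinal stem cells, camera gave an adjusted p of 8.76e-06, and adjusted p = 0.420 with an estimated correlation. Camera on gastric and Brunner gland genes gave an adjusted p of 1.61e-08, and adjusted p = 0.138 with an estimated correlation. For inflammation genes, camera gave an adjusted p of 5.06e-10, and adjusted p = 0.408 with an estimated correlation. Camera on fetal-like and YAP targets gave an adjusted p of 3.39e-06, and adjusted p = 0.359 with an estimated correlation. Endothelial genes rose in 13 of 15 cases (14 adjusted over the list alone), such as Esam (2.01 ± 0.21, 1.60e-05) and Egfl7 (2.27 ± 0.26, 2.35e-05). For endothelial genes, camera gave an adjusted p of 0.000565, and adjusted p = 0.547 with an estimated correlation. All 15 smooth muscle genes fell (15 adjusted over the list alone, Mylk -3.97 ± 0.38, 9.90e-06), and 8 of 10 ileum genes fell and 1 rose (8 and 1 adjusted over the list alone). Camera on smooth muscle genes gave an adjusted p of 3.87e-09, and adjusted p = 0.408 with an estimated correlation. For ileum genes, camera gave an adjusted p of 0.000565, and adjusted p = 0.420 with an estimated correlation. The ileal bile acid binding protein gene Fabp6 went from 9112 to 14.6 CPM (-9.29 ± 1.60, adjusted p = 0.000465) and the goblet cell gene Clca1 from 3628 to 35.8 CPM (-6.66 ± 0.85, adjusted p = 6.26e-05). Lcn2 rose to 1375 CPM (9.09 ± 0.99, adjusted p = 2.25e-05) and S100a9 to 324 CPM (10.11 ± 1.02, adjusted p = 1.42e-05). Without tumor 1323 the log2 fold change of Fabp6 was -10.43 and that of S100a9 9.09. Among p53 targets 9 of 39 rose and 12 fell (9 and 12 adjusted over the list alone), with Plk2 (2.17 ± 0.34, 0.000219) and Pvt1 (2.59 ± 0.48, 0.000691) higher and Sesn1 (-2.96 ± 0.30, 1.24e-05) and Cdkn1a (-1.94 ± 0.32, 0.000289) lower. Camera on p53 targets gave an adjusted p of 0.131, and adjusted p = 0.586 with an estimated correlation. By edgeR 9650 genes changed, 5044 higher and 4606 lower, and all 53 named genes that passed did so under every planned setting.

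In organoids the H2BdIEC comparison asked what differed from controls in cultured epithelium. Of 40 p53 targets 12 rose and 0 fell (18 rose and 3 fell adjusted over the list alone, median log2 0.25). For p53 targets, camera gave an adjusted p of 1.35e-06, and adjusted p = 0.313 with an estimated correlation. Eda2r stood at 35.2 ± 1.92 against 8.20 ± 0.124 CPM (SD, n = 3 each, log2 2.09 ± 0.13, adjusted p = 2.17e-06), Ccng1 at 589 ± 83.5 against 301 ± 25.2 CPM (0.96 ± 0.10, adjusted p = 0.000150), and the stress-response gene Trp53inp1 at 89.8 against 34.7 CPM (1.36 ± 0.12, adjusted p = 4.34e-05). Plk2 (1.36 ± 0.10, 8.11e-06), Phlda3 (0.87 ± 0.17, 0.0157) and Zmat3 (0.65 ± 0.08, 0.000676) rose as well. The p53 count was 7 without control A, with only these groups in the fit, and with the replicate letter as a block. By edgeR, 0 of 27 interferon-stimulated genes changed (3 fell adjusted over the list alone, median log2 -0.42), against 10 lower and 0 higher at unadjusted p under 0.05 and 2 lower and 0 higher by DESeq2. Camera on interferon-stimulated genes gave an adjusted p of 0.00798, and adjusted p = 0.528 with an estimated correlation. Isg15, for example, had a log2 fold change of -1.2 ± 0.32 (adjusted p = 0.0594).

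Paneth cell genes fell in 5 of 12 cases (6 adjusted over the list alone), including Lyz1 (205 against 450.4 CPM, -1.13 ± 0.08, adjusted p = 5.17e-06) and Mmp7 (14.8 against 29.9 CPM, -1.02 ± 0.11, adjusted p = 0.000184), and 3 fell with the letter as a block. For Paneth cells, camera gave an adjusted p of 0.000195, and adjusted p = 0.431 with an estimated correlation. Enteroendocrine genes rose in 5 of 18 cases (8 adjusted over the list alone), such as the hormone gene Gip (136 against 82.8 CPM, 0.72 ± 0.10, adjusted p = 0.00179) and the chromogranin gene Chga (0.54 ± 0.11, 0.0147). Camera on enteroendocrine cells gave an adjusted p of 0.00798, and adjusted p = 0.431 with an estimated correlation. The enteroendocrine count was 2 without H2BdIEC B or control C, 3 without control A or with only these groups, and 1 with the letter as a block. The cytochrome P450 genes Cyp3a11 (440.2 against 97.5 CPM, 2.17 ± 0.24, adjusted p = 0.000853) and Cyp2c29 (293 against 86.2 CPM, 1.76 ± 0.20, adjusted p = 0.000676) and the goblet cell gene Zg16 (1.59 ± 0.12, 1.51e-05) rose, while the securin gene Pttg1 (9.66 against 35.7 CPM, -1.86 ± 0.12, adjusted p = 3.46e-06) and the transcription factor gene Klf9 (11.2 against 31.8 CPM, -1.53 ± 0.10, adjusted p = 3.99e-06) fell. Markers of the ileum averaged 2.44 to 3.06 log2 CPM in H2BdIEC libraries and 1.75 to 2.23 in controls, and mitochondrially encoded genes 9.28 to 9.92 and 10.10 to 10.39. By edgeR 637 of 15701 genes changed, 327 higher and 310 lower. The count was 286 without H2BdIEC B, 319 without control B, 1185 without H2BdIEC A, the library with the fewest counts of the organoids, 242 with only these groups, 166 with the letter as a block and 1494 with no low-count filter. Of 31 named genes that passed, 19 passed under every planned setting, while the block by letter ended 10 calls and the removals of H2BdIEC B and control A ended 4 and 3. The H2BdIEC organoids expressed Y-linked genes and the control and H2Bp53dIEC organoids expressed Xist, so sex and the H2BdIEC genotype coincide.

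Targets of p53 were lower in H2Bp53dIEC than in H2BdIEC organoids: 30 of 40 fell and 2 rose (32 and 2 adjusted over the list alone), with a median log2 fold change of -0.85. For p53 targets, camera gave an adjusted p of 4.46e-17, and adjusted p = 0.0189 with an estimated correlation. Eda2r stood at 0.206 ± 0.199 against 35.2 ± 1.92 CPM (SD, n = 3 each, log2 -7.43 ± 0.24, adjusted p = 1.87e-09), Phlda3 at 1.24 ± 0.388 against 53.4 ± 15.6 CPM (-5.46 ± 0.26, adjusted p = 7.15e-08) and Ccng1 at 84.3 ± 4.05 against 589 ± 83.5 CPM (-2.80 ± 0.11, adjusted p = 6.80e-09). Cdkn1a (69.7 against 311 CPM, -2.16 ± 0.10, adjusted p = 3.75e-08), Gdf15 (4.44 against 37.1 CPM, -3.09 ± 0.22, adjusted p = 2.20e-06) and Zmat3 (-2.41 ± 0.09, 5.37e-09) fell. Interferon-stimulated genes rose in 25 of 27 cases and fell in 0 (25 adjusted over the list alone, median log2 1.64). Camera on interferon-stimulated genes gave an adjusted p of 4.17e-12, and adjusted p = 0.260 with an estimated correlation. Rsad2, which encodes viperin, stood at 11.3 ± 0.332 against 0.866 ± 0.409 CPM (3.81 ± 0.25, adjusted p = 7.94e-07), Xaf1 at 17.3 ± 0.883 against 1.2 ± 0.720 CPM (4.04 ± 0.34, adjusted p = 5.71e-06) and the chemokine gene Cxcl10 at 4.67 ± 0.220 against 0.354 ± 0.0247 CPM (3.70 ± 0.29, adjusted p = 3.18e-06), and Ifitm3 rose by 1.93 ± 0.13 (112 against 28.7 CPM, 1.0e-06). On GRCm38, Cdkn1a (ENSMUSG00000023067) spans chromosome 17, 29090976 to 29100727, Rsad2 (ENSMUSG00000020641) spans chromosome 12, 26442746 to 26456452, and Cxcl10 (ENSMUSG00000034855) spans chromosome 5, 92346638 to 92348889.

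Wnt targets rose in 12 of 18 cases (14 adjusted over the list alone), among them Ephb3 (1.13 ± 0.10, 1.08e-05), Prox1 (1.60 ± 0.17, 3.18e-05) and the feedback gene Axin2 (231 against 123 CPM, 0.90 ± 0.10, adjusted p = 8.17e-05), and stem cell genes in 13 of 18 (15 adjusted over the list alone), with Olfm4 at 879.7 against 292 CPM (1.59 ± 0.10, adjusted p = 6.41e-07) and Ascl2 at 1.45 ± 0.15 (2.85e-05). For Wnt targets, camera gave an adjusted p of 3.53e-07, and adjusted p = 0.0189 with an estimated correlation. Camera on intestinal stem cells gave an adjusted p of 3.22e-06, and adjusted p = 0.0900 with an estimated correlation. S-phase genes rose in 16 of 26 cases and fell in 1 (19 rose adjusted over the list alone, median log2 0.34), with the helicase subunit gene Mcm7 at 0.58 ± 0.09 and the ribonucleotide reductase gene Rrm2 at 0.48 ± 0.06 (adjusted p = 0.000756 and 0.000217). For S phase genes, camera gave an adjusted p of 3.22e-06, and adjusted p = 0.0912 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 21 cases (13 adjusted over the list alone), and antimicrobial and MHC class II genes in 8 of 11 (8 adjusted over the list alone), such as Reg3b (1.46 ± 0.14, 1.9e-05) and H2-Ab1 (1.03 ± 0.14, 0.000202), with 5 under a filter of at least 1 CPM. Camera on cholesterol synthesis genes gave an adjusted p of 0.000135, and adjusted p = 0.174 with an estimated correlation. For antimicrobial and MHC class II genes, camera gave an adjusted p of 4.18e-05, and adjusted p = 0.0912 with an estimated correlation. Immediate early and heat shock genes fell in 11 of 16 cases (12 adjusted over the list alone), such as Hsph1 (-1.07 ± 0.07, 6.41e-07) and Atf3 (-1.31 ± 0.13, 2.85e-05), and genes of the ATF4 and unfolded protein response in 11 of 20 (11 adjusted over the list alone), with Chac1, a glutathione-degrading enzyme gene, at 9.91 against 39.1 CPM (-2.01 ± 0.16, adjusted p = 3.38e-06) and Ddit3, which encodes the stress factor CHOP, at -1.07 ± 0.12 (6.03e-05). Camera on immediate early and heat shock genes gave an adjusted p of 1.63e-05, and adjusted p = 0.132 with an estimated correlation. For ATF4 and unfolded protein response genes, camera gave an adjusted p of 2.83e-05, and adjusted p = 0.174 with an estimated correlation. The 3 tested genes of stomach and Brunner glands averaged 1.88 to 2.19 log2 CPM in H2Bp53dIEC, -0.30 to -0.03 in H2BdIEC and -0.46 to -0.24 in control organoids. The fetal liver gene Afp fell from 105 to 9.29 CPM (-3.49 ± 0.11, adjusted p = 1.87e-09).

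Against control organoids the H2Bp53dIEC organoids showed 28 of 40 p53 targets lower and 2 higher (28 and 2 adjusted over the list alone), with Cdkn1a at 69.7 against 293 CPM (-2.07 ± 0.10, adjusted p = 1.02e-07). Camera on p53 targets gave an adjusted p of 6.84e-11, and adjusted p = 0.0498 with an estimated correlation. Interferon-stimulated genes rose in 20 of 27 cases (21 adjusted over the list alone), including Rsad2 (11.3 against 1.26 CPM, 3.15 ± 0.20, adjusted p = 5.26e-07) and Xaf1 (3.85 ± 0.30, 2.09e-06). For interferon-stimulated genes, camera gave an adjusted p of 1.27e-08, and adjusted p = 0.304 with an estimated correlation. S-phase genes rose in 20 of 26 cases (22), Wnt targets in 12 of 18 (13) and stem cell genes in 12 of 18 (13), the count in each bracket being adjusted over the list alone. Camera on S phase genes gave an adjusted p of 5.39e-08, and adjusted p = 0.0667 with an estimated correlation. For Wnt targets, camera gave an adjusted p of 1.12e-05, and adjusted p = 0.0498 with an estimated correlation. Camera on intestinal stem cells gave an adjusted p of 6.27e-06, and adjusted p = 0.0802 with an estimated correlation. The Wnt inhibitor gene Apcdd1 rose by 1.65 ± 0.16 (1.24e-05) and Sfrp5 by 2.78 ± 0.17 (25.1 against 3.64 CPM, 3.50e-07). Genes of the ATF4 and unfolded protein response fell in 12 of 20 cases (13 adjusted over the list alone) and immediate early and heat shock genes in 11 of 16 (11 adjusted over the list alone). For ATF4 and unfolded protein response genes, camera gave an adjusted p of 8.44e-07, and adjusted p = 0.132 with an estimated correlation. Camera on immediate early and heat shock genes gave an adjusted p of 8.44e-07, and adjusted p = 0.0978 with an estimated correlation. The amphiregulin gene Areg went from 178 to 31.4 CPM (-2.50 ± 0.14, adjusted p = 1.65e-07). By edgeR 4601 genes changed against H2BdIEC (2413 of them lower) and 5230 against controls (2621 higher, 2609 lower). With upper-quartile factors 2498 were higher and 2077 lower against H2BdIEC, so which direction held more genes there depended on the scaling. Against controls 2971 were higher and 2328 lower with these factors, and 2608 and 2624 with DESeq2 size factors. The 4601 became 2982 without H2Bp53dIEC 1 and 3039 without H2Bp53dIEC 2. All 52 and 47 named genes that passed did so under every planned setting. The titles of the H2Bp53dIEC organoids lack the prefix shared by the other organoids, so their culture or preparation could not be separated from genotype.

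**Figure D4:**
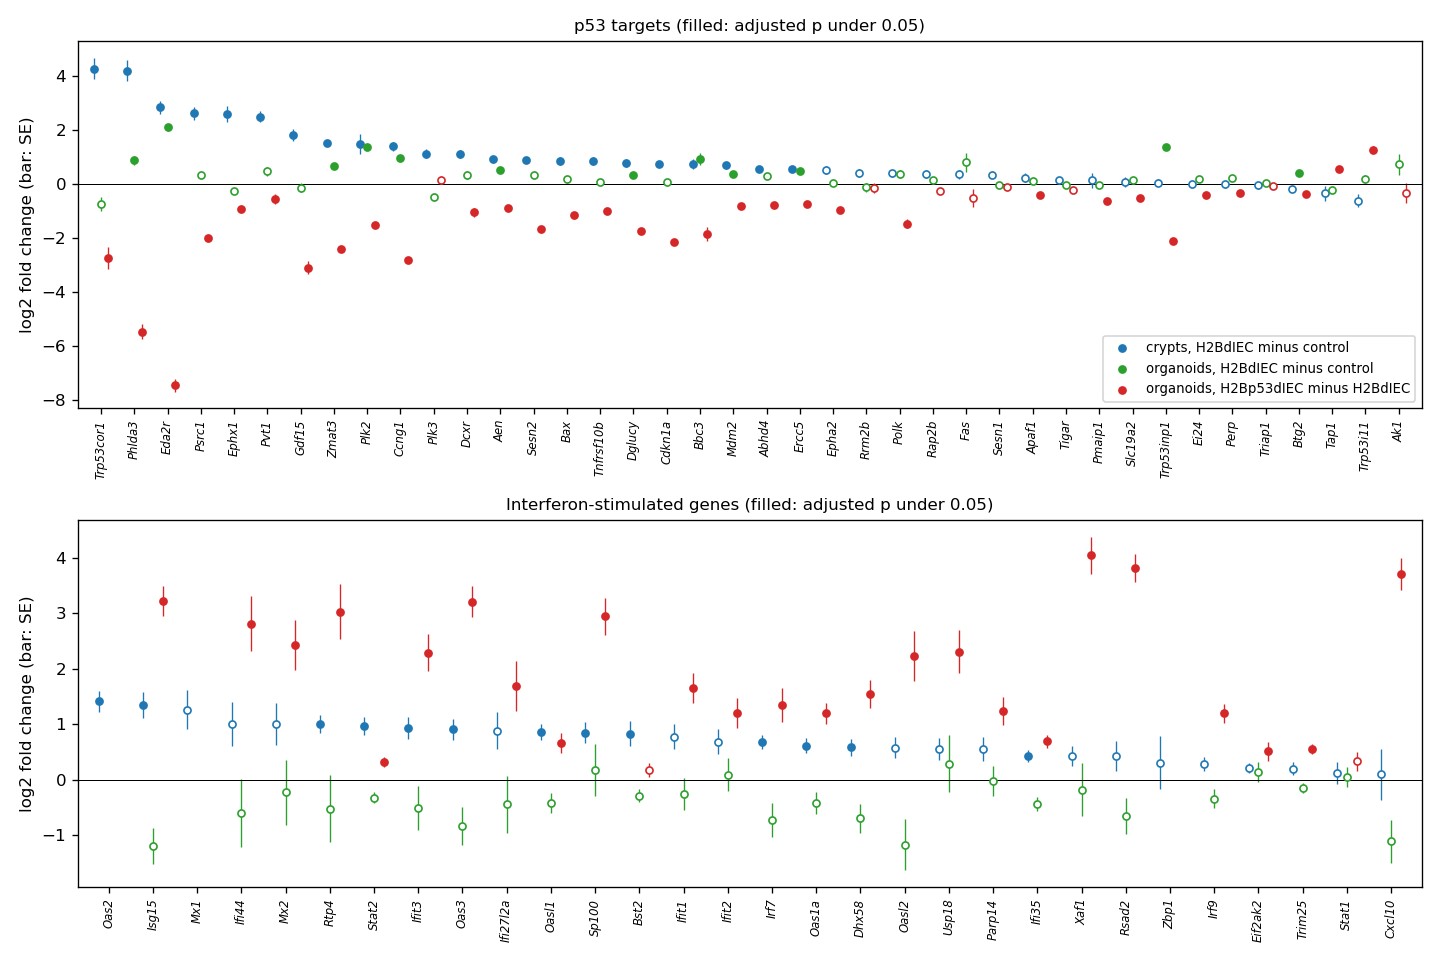
Log2 fold changes (vertical axes, whiskers: SE) of the tested members of the p53 target and interferon-stimulated lists for H2BdIEC minus control crypts (blue), H2BdIEC minus control organoids (green) and H2Bp53dIEC minus H2BdIEC organoids (red), with filled points at adjusted p under 0.05. In the red series 30 p53 targets were lower and 25 interferon-stimulated genes were higher, and points are missing where a gene was not tested.

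The effect of the H2BdIEC genotype was compared between crypts and organoids by an interaction contrast. The effect on p53 targets was higher in crypts for 10 of 40 genes and higher in organoids for 2 (14 and 2 adjusted over the list alone). For p53 targets, camera gave an adjusted p of 1.61e-05, and adjusted p = 0.126 with an estimated correlation. The differences in log2 fold change, crypts minus organoids, were 3.36 ± 0.45 for Phlda3 (0.00152), 2.28 ± 0.28 for Psrc1 (0.000384), 2.86 ± 0.36 for Ephx1 (0.00131), 1.99 ± 0.30 for Gdf15 (0.00227), and -1.30 ± 0.17 for Trp53inp1 (0.000686). Interferon-stimulated genes differed in 6 of 30 cases, all higher in crypts (11 adjusted over the list alone and 10 by DESeq2), among them Stat2 (1.30 ± 0.22, 0.00536) and Isg15 (2.56 ± 0.46, 0.00720), and the count was 2 without organoid H2BdIEC B and 3 without organoid control B. Camera on interferon-stimulated genes gave an adjusted p of 2.36e-08, and adjusted p = 0.435 with an estimated correlation. Stem cell genes differed in 4 of 18 cases, all lower in crypts (7 adjusted over the list alone), with Lgr5 at -1.65 ± 0.28 and Olfm4 at -1.11 ± 0.23 (0.00578 and 0.0148), and 7 differed without crypt H2BdIEC 1. For intestinal stem cells, camera gave an adjusted p of 0.00111, and adjusted p = 0.448 with an estimated correlation. By edgeR 690 of 17163 genes differed, 394 with the higher value in crypts and 296 with the higher value in organoids, and DESeq2 called 1356. The count was 457, 1053 and 414 without crypt controls 1, 2 and 3, 439 and 248 without organoid H2BdIEC A and B, and 447, 218 and 318 without organoid controls A, B and C. Of 32 named genes that passed, 23 passed under every planned setting, and the removals of organoid H2BdIEC B, control B and control C ended 8, 6 and 5 calls. The contrast removes handling differences between the sets only where these act alike on both genotypes. In organoids sex coincides with the H2BdIEC genotype, and in crypts the proximal scores of the genotypes did not overlap. The differences between crypts and organoids can therefore carry sex and region as well as genotype.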

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

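The tests of region over all p53 targets, of sex, of the share of smooth muscle, of the region of the adjacent tissue, of the sex of the organoid donors, of immune cells and of preparation were chosen only after the results were seen, while those of region over the 22 targets and of depth in crypts and of other splits of the libraries were set earlier.

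The higher p53 targets in H2BdIEC crypts were weighed against the intestinal region sampled, depth and sex. With the proximal marker score as a covariate, the median log2 fold change of all 39 tested targets was 0.6712 (median SE 0.367), against 0.683 (median SE 0.146) without it, and 33 were positive in both fits. The 22 that had passed had 1.061 (median SE 0.405), against 1.11 (median SE 0.157), but they had been chosen as higher, so they exclude nothing although their median met the bound of 2 SE set earlier. Only 1 of the 22 still passed, because the SE rose where the scores of both groups do not overlap. Camera gave an adjusted p of 1.12e-09, or adjusted p = 0.0807 with an estimated correlation, so region and genotype cannot be told apart here. After thinning to equal depth 21 of the 22 passed and with sex as a covariate 22 of 22 did. These 22 had been chosen as higher, so that alone excludes neither depth nor sex. Over all 39 tested targets, the count called higher stayed within 1.5 times of 22 in both fits, which argues against both. Region or a response to the H2BdIEC genotype may account for the rise, and the higher mitochondrial share and the pancreas transcripts were not tested as explanations.

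The higher Wnt targets in tumors were weighed against a smaller share of smooth muscle and against the region of the adjacent tissue. A smaller share of muscle alone would raise the other cell types alike. The enterocyte list instead had a median log2 fold change of -2.54 (SE 0.273 over its members), near the -2.45 of smooth muscle. That argues against a smaller muscle share as the only change. It cannot show whether less muscle added to the rise, since enterocytes may have fallen for another reason. In mouse 1323, whose adjacent tissue had proximal markers, the Wnt targets still differed by a median of 2.84, against 2.38, 3.63 and 2.92 in the other mice. Only in mouse 1323 did the ileum and proximal means of adjacent tissue lie within 1 log2 unit (5.60 and 5.22). In mouse 1319 they were 8.11 and 4.21. With 1 such mouse, and with gastric and Brunner gland genes in the tumors, tumor and region cannot be told apart for this list. Tumor growth as a biological explanation stays open and untested.

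The higher interferon-stimulated genes in H2Bp53dIEC organoids were weighed against donor sex, immune cells and preparation. Against control organoids, which like them expressed Xist, 20 of 27 rose, which argues against donor sex. The 6 tested of 35 leukocyte genes, fixed before the data were examined, had a median log2 fold change of 0.633 (SD 0.464) against 1.64 for the interferon-stimulated list, and their list summed to 17.0 CPM against 10.6 in H2BdIEC, with Cd14 (5.95 against 3.99) and Lck (3.88 against 1.60) most abundant, while the interferon-stimulated list summed to 784 against 438 CPM. The sums of the lists rose by similar factors and the median rests on 6 weakly expressed genes, so neither decides on immune cells as the source. Ptprc stood at 0.0634 CPM and Cd3e and Tyrobp at 0 in H2Bp53dIEC organoids, so these libraries held little leukocyte RNA. The titles of 0 H2Bp53dIEC libraries carry the prefix of the other organoids, so a culture or preparation batch cannot be told apart from genotype. Rnaseh2b was also lower in H2Bp53dIEC than in H2BdIEC organoids, so the 2 genotypes differ in more than p53. Batch, the loss of p53 or the lower Rnaseh2b may account for the pattern, and these cannot be separated here.

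In crypts and in tumors against controls, the real split gave 1464 and 9650 changed genes. The highest of the other 34 of the 35 splits gave 0 and 0. A share of 1 in 35 is the smallest these splits can give, so it argues against chance without excluding it. The other splits mix the 2 groups, which widens their spread and lowers their counts where the groups differ. In adjacent tissue against controls the real split gave 189 and the highest other 1, but the 189 became 0 without control 1321 and 2 without control 1316, so that count rests on single libraries. Tumors and adjacent tissue are paired by mouse, and the 8 splits that part all 4 pairs are too few for a share under 0.05. The real split gave 8293 there and the highest other 0, or 1 among the 34 others of all 35 splits. For the interaction the real count of 690 was reached by 1 of 80 splits, the real one, and the highest other gave 311. The other splits were drawn at random and shuffled genotype within both sets. They therefore stand for no genotype effect in either set, not for equal effects in both. The organoid comparisons have 10 splits each, too few for a share under 0.05. The real counts there were 637, 4601 and 5230 and the highest others 4, 0 and 0.

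Single libraries stood far from the other 3 of their group in 21 of the 288 groups of 4 values examined, where chance gives about 1 in 20, or 14.4. In crypt control 4 mitochondrially encoded genes took 10.39% of counts (4.33% to 5.09% in the others) and the top 10 genes 18.78% (10.9% to 11.0%), and Gsta4 stood at 35.89 CPM. Crypt control 3 had Zmat3 at 15.51 CPM, H2BdIEC 3 had Gsdmc4 at 2.386 CPM, and H2BdIEC 2 had a pancreas list mean of 5.702 log2 CPM. Tumor 1322 had Notum at 1121 CPM (195 to 293 in the others), Bpifb1 at 2411 CPM (52.9 to 161), Sox4 at 94.01 CPM and Phgdh at 119.8 CPM, and tumor 1323 had Cybrd1 at 10.32 CPM. Adjacent 1319 had Hbb-bs at 371.1 CPM, Hba-a1 at 142.8 CPM, Alas2 at 32.55 CPM and Lcn2 at 150.4 CPM. Adjacent 1349 had Sox4 at 18.34 CPM and Slc7a5 at 33.85 CPM, and adjacent 1323 had Bpifb1 at 0.7868 CPM. Control 1320, the library with the fewest counts, had Rnaseh2b at 24.09 CPM and Hba-a1 at 8.028 CPM, and control 1315 had Mt1 at 297.5 CPM.

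The H2BdIEC effect differed between crypts and organoids in 690 genes by the interaction test. The log2 effect in crypts minus that in organoids was 3.355 for Phlda3, 2.285 for Psrc1, 5.012 for Trp53cor1, 1.988 for Gdf15, 2.864 for Ephx1 and -1.298 for Trp53inp1 among p53 targets. It was 1.303 for Stat2 and 2.556 for Isg15 among interferon-stimulated genes, and -1.113 for Olfm4, -1.652 for Lgr5 and -1.109 for Smoc2 among stem cell genes. It was -2.162 for Zg16, which rose in H2BdIEC organoids. Other genes named in crypts differed by -3.531 (Bmp3), 3.4 (Acta1), 5.017 (S100g), 3.748 (Pdx1), 7.217 (Akp3) and 3.854 (Slc40a1). Pdx1 and Slc40a1 are members of the proximal small intestine list. The contrast does not separate genotype from region in crypts or from sex in organoids.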

How the results depend on the processing

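The fits with the proximal score as a covariate, with sex, thinned libraries, both libraries of a mouse left out, control 1320 left out alone or with adjacent 1323, and X and Y genes left out were chosen after seeing the data. In the alternatives fixed before the data were examined, 0 of the named genes that passed changed sign, and for tumor against adjacent, tumor against control and H2Bp53dIEC against control the count of changed genes stayed within 1.5 times of its value (6603 to 8633, 8396 to 10000 and 3622 to 7112).

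With sex as a covariate 1239 genes changed in crypts, and after thinning 1311 did. By fry the p53 list had adjusted p = 6.77e-06 in crypts, 0.00443 in H2BdIEC organoids and 2.42e-06 for H2Bp53dIEC against H2BdIEC. The interferon-stimulated list had adjusted p = 0.0255, 0.366 and 0.00163 by fry, so it did not pass in H2BdIEC organoids.

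DESeq2 called more genes in crypts (2390), adjacent tissue against controls (902) and the interaction (1356). Data were also simulated with the spread estimated by edgeR, with 200 random genes and the p53 list changed. There, unchanged genes made up 17.5% of DESeq2 calls in crypts and 28.0% in adjacent tissue against controls. With edgeR the shares were 8.67% and 4.08%. Such shares depend on how many genes change, so they are not error rates of the real calls. Fitting only the groups compared gave 441 genes in adjacent tissue and 242 in H2BdIEC organoids, a block by organoid letter gave 166, and no low-count filter gave 1494 in H2BdIEC organoids. The proximal covariate left 11 genes in crypts, and leaving out control 1320 and adjacent 1323 left 33. The cause was not tested, except that the covariate widened the SE. Leaving out 1 library at a time gave 481 to 1839 genes in crypts, 0 to 223 in adjacent tissue, 286 to 1185 in H2BdIEC organoids, 2982 to 5483 for H2Bp53dIEC against H2BdIEC and 218 to 1053 for the interaction. For 0 genes by edgeR without control 1321, 2075 had an unadjusted p under 0.05.

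Changes of direction occurred in 4 genes, of which Papss2 alone had passed (adjusted p = 0.0355 in crypts). With the proximal covariate its log2 fold change turned from 2.29 to -0.40 (adjusted p = 0.932), and that of Onecut2 from 0.99 to -0.43 (adjusted p = 0.848). In tumors against adjacent tissue that of Rnaseh2b turned from 0.10 to -0.07 without mouse 1323 (adjusted p = 0.903), and over removals of 1 library its adjusted p was 0.481 to 0.974. There Trp53 turned from -0.10 to 0.07 without mouse 1319 (adjusted p = 0.882), and its adjusted p was 0.245 to 0.990 with 1 library left out. In the interaction Trp53 turned from -0.11 to 0.01 without organoid H2BdIEC C, and its adjusted p was 0.453 to 1.0 with 1 library left out. The cause was not tested.

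In tumors against controls the median log2 fold change over all genes was 0.151 with DESeq2 size factors, 0.150 with upper-quartile factors, 0.165 with no low-count filter and -0.204 by DESeq2. Depth limits control 1320 most, where 3 counts correspond to 7.47 CPM, against at most 0.520 CPM in any other library. On simulated data edgeR recovered 68.1% of 2-fold changes in crypts, 10.4% in adjacent tissue against controls and 82.1% in H2BdIEC organoids. Paired tumor and adjacent libraries of 1 mouse had correlations of their deviations across genes, which are not independent replicates, of 0.156, -0.164, 0.120 and 0.064.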

Other observations

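The test of shared genes was set before the result was seen. The hypothesis was that the H2BdIEC genotype changes some of the same genes in crypts and in organoids. Of 12474 genes tested in both sets, 659 were higher in H2BdIEC crypts and 269 in H2BdIEC organoids, and 58 were higher in both, against 14.2 for independent lists, a ratio of 4.081. Among the 58 were 10 p53 targets, namely Aen, Bbc3, Ccng1, Dglucy, Eda2r, Ercc5, Mdm2, Phlda3, Plk2 and Zmat3. They also held Clu, which encodes clusterin, the interleukin receptor antagonist gene Il1rn, the DNA repair gene Mgmt and the glutathione transferase genes Gsta1, Gsta2 and Gsta4, whose copies share reads. Lower in both were 34 genes, against 13.8 for independent lists, a ratio of 2.46, among them Rnaseh2b, the stem cell gene Olfm4 and the Paneth cell gene Lyz1. A further 38 genes changed in opposite directions, against 28.0 for independent lists. Genes are not independent of each other, so the ratios carry no p value.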
